A study of Mus musculus with 12 samples.

How the data were processed

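Small RNA was measured in the livers of male C57BL/6 mice that were given chow or a diet labelled HFCF, an abbreviation that the labels do not spell out. Mice were sampled after 1 month on the diet (3 months of age) or after 3 months on the diet (6 months of age). Time on the diet and age thus moved together. By these figures the age at the start of the diet was also higher in the groups sampled after 3 months. Each of the 4 groups held 3 libraries, described in the design text as biological replicates, and the 12 libraries were assigned to groups from their labels. The labels' protocols name Trizol and a column kit for RNA extraction and a multiplex small RNA library kit, whereas the design text names a stranded total RNA kit with ribosomal RNA removal and single reads of 50 cycles. Which of them was used is not settled by these sources; miRNAs were the most abundant class in the table.

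The deposited table held whole-number read counts and FPKM values, per the file headers, for 3717 genes with Ensembl identifiers. The aligner, the counting tool and the use of strand in counting are not given in the sources used here; the genome build was mm10, per the submitters' processing notes. Every gene in the table had a count of at least 10 in 1 or more libraries. The authors' FPKM values were used only to work out the library size behind them, and in no test. The table total was 99.5% to 99.7% of that size. Counts were per precursor locus, so the arms of a hairpin were not separated, and miRNAs with near-identical copies (let-7a, let-7c, let-7f, miR-26a, miR-29b, miR-30c, miR-103, miR-128, miR-181a, miR-181b and miR-194 among them) are uncertain as to copy. Overlapping genes had counted the same reads, which affected 156 long or unmatched genes that overlap a small RNA gene. At 18 miRNA loci the opposite strand holds another miRNA locus, and without knowledge of the strand setting the pair cannot be separated; Mir126, Mir299b, Mir337, Mir451 and Mir486 are among them. The locus AC116595.1 was assigned to miR-378a by its coordinates on the opposite strand, and AC121784.1 to miR-409, AC165361.1 to let-7e and AC147162.1 to let-7f-1 in the same way, so these assignments are uncertain. Of the identifiers, 3617 matched GENCODE release M21, which also gave gene names, host genes and coordinates on mm10. miR-122, miR-146b and miR-199a are not analysed here.

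The main fits used the 259 miRNA loci, with the library size taken as their sum. This sum ran from 1434214 to 3122907 counts, within table totals of 2539388 to 5255906. After edgeR's filterByExpr by group, 227 loci were tested. Scaling was by TMM and the test was edgeR's quasi-likelihood test with robust dispersion, over all 12 libraries with 1 mean per group, and with Benjamini-Hochberg adjusted p under 0.05 called changed. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the test's F value. Levels are TMM-scaled CPM, relative to the sum over miRNA loci, given as mean ± SD. In data simulated from these libraries, the test for the comparison of diets at 3 months on 227 loci recovered 26.7% of loci changed 1.5-fold, 46.7% of those changed 2-fold and 100% of those changed 4-fold, with 2 false calls, and called 0 loci where nothing was changed at 1 month. Small changes are thus often missed at this depth and number of mice.

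Before the data were examined, 18 lists of miRNAs were fixed: hepatocyte-enriched, leukocyte-enriched, mesenchymal, endothelial, biliary epithelial (the miR-200 family), erythroid, muscle, pancreas and neuronal miRNAs, the miR-29 and let-7 families, the miR-183 (miR-183, miR-96 and miR-182), miR-17/92, Dlk1-Dio3 and Sfmbt2 clusters, lipid and sterol metabolism, and miRNAs reported raised or reported lowered in fatty or fibrotic liver. Lists overlap; miR-183, miR-96 and miR-182, for example, also stand in the list reported raised. Lists with at least 3 measured loci were tested against the other miRNAs with limma's camera at a preset correlation of 0.01 on voom values. Camera with an estimated correlation and limma's fry, which tests the list alone, were run beside it, and p-values were adjusted over the lists of a comparison. At 1 month the estimated correlation was 0.608 for Dlk1-Dio3, 0.854 for the miR-183 cluster, 0.968 for the erythroid list and 0.335 for the list reported raised. It was 0.0748 for let-7 and -0.307 for the neuronal list. Where it lies far above 0.01, camera p-values at the preset are too small. Lists said to pass in camera passed at the preset. Named miRNAs follow a rule fixed at the same time. For each comparison of diets they are the up to 12 largest changes in each direction among miRNAs that passed, reached 10 CPM in 1 of the groups and had all 3 HFCF libraries on 1 side of the chow mean; where fewer than 10 passed, the smallest p-values filled the number up to 10. In the other comparisons they are the 5 smallest p-values, and 22 miRNAs of interest in liver were named whatever their p. Other members of the fixed lists that are named as examples, and any miRNA or gene named beyond these, were chosen after their values were seen.

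The alternatives were DESeq2's size factors, library totals alone, scaling without the most abundant miRNA, all genes of the table in 1 fit, no filter, a filter at 10 CPM, DESeq2, limma-voom, only the libraries compared, the replicate number as a block, no robust dispersion, an adjusted p under 0.1, and leaving out each of the 12 libraries in turn. Those written for normalized values did not apply to counts. Library totals in place of TMM moved the median log2 fold change of all miRNAs to 0.27 for diet at 3 months, 0.36 for the difference of the diet effects and 0.35 for time in HFCF mice. The mean TMM factor was 1.15 in HFCF mice at 3 months, and 0.979, 0.918 and 0.97 in chow mice at 1 month, HFCF mice at 1 month and chow mice at 3 months. Changes are therefore relative to the typical miRNA. Shares of RNA classes were compared by exact permutation tests, 2-sided, for which 3 libraries against 3 allow no p under 0.1. Within groups, log2 CPM values correlated at 0.985 to 0.995 and no pair of libraries matched within sampling noise (lowest chi-square 24.1 per degree of freedom). Pairs from different groups also reached 0.995, and the lowest of all pairs was 0.954. HFCF replicate 1 at 3 months correlated at 0.987 with each library of its group and at 0.991 with HFCF replicate 3 at 1 month.

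Fragments of longer genes in the table were tested with edgeR in the same way, 1552 protein-coding genes and 257 snoRNA and scaRNA genes. The lists of protein-coding genes (sterol synthesis and uptake, leukocyte, mesenchymal and matrix, biliary epithelial, pancreatic acinar and hepatocyte transcripts, lipid storage and peroxisome proliferator response, fatty acid synthesis, bile acid synthesis and transport) were written after the miRNA results were known and before the values of these genes were seen. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.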

Results

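The series profiled miRNAs in the liver in a mouse model of nonalcoholic steatohepatitis, the inflammatory form of fatty liver disease. Libraries came from chow-fed and HFCF-fed mice after 1 month or 3 months on the diet, 3 mice in each of 4 groups. The table held between 2539388 and 5255906 counts per library, of which miRNA loci took 1434214 to 3122907. The counts of the miRNA loci used here, which do not include miR-122, were dominated by a few miRNAs. Mir21, Mir148a and Mir192 together took 49.7% to 58.7% of these counts. Among these loci Mir21 was the most abundant in every library except HFCF replicate 1 at 3 months, where Mir148a was. Among genes that did not share reads with a smaller gene, miRNAs made up 81.7% ± 4.28 (SD, n = 3) of counts in HFCF mice and 77.9% ± 5.02 in chow mice at 1 month (exact permutation p = 0.4). The shares were 81.8% ± 4.36 and 81.4% ± 1.22 at 3 months (exact permutation p = 0.9). The snoRNA and scaRNA share was 10.7% against 13% at 1 month (exact permutation p = 0.3) and 9.86% against 11.6% at 3 months (exact permutation p = 0.4). The smallest p that 3 mice against 3 allow is 0.1, so no difference in class shares could pass at 0.05.

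The 3 HFCF libraries at 3 months lay apart from all others on the first principal component, which held 48.9% of the variance, at 5.91, 9.06 and 9.35. The HFCF libraries at 1 month lay at -1.91, -0.06 and 1.59, and the chow libraries between -6.20 and -2.43. A single chow library at 1 month, replicate 2, stood apart on the second component (15.5% of the variance) at 7.23. That library had 44.7 CPM of Mir375, a miRNA of pancreatic islets and other endocrine cells, against 2.21 to 5.37 CPM in the other 11 libraries. It also had 1389 CPM of Mir10b (others 33.1 to 169), 262 CPM of Mir200c, an epithelial miRNA (others 42.7 to 83.9), and 34770 CPM of Mir143, a smooth muscle miRNA (others 11240 to 19970). Replicate 1 of the same group had the highest level of the red-cell miRNA Mir451, 4437 CPM against 1299 to 3610 CPM in the others. Mir10b, Mir200c and Mir143 were singled out after their values were seen.

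**Figure D1:**
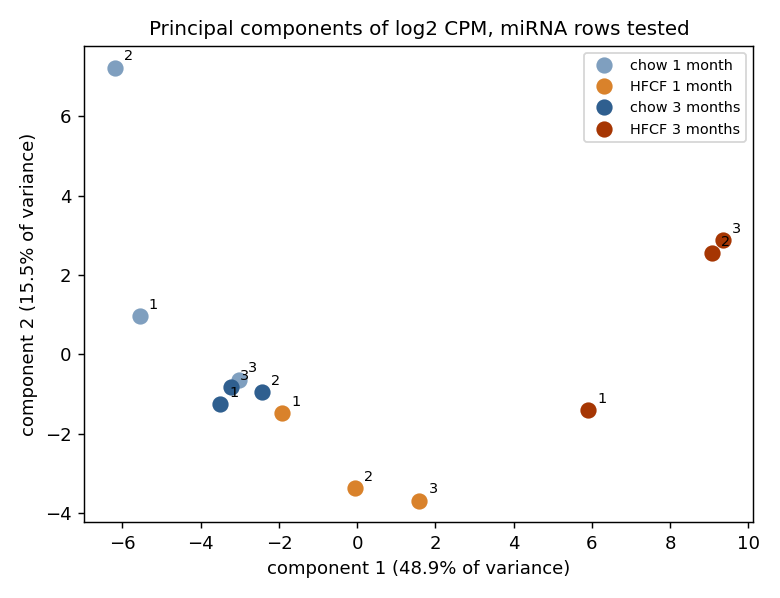
Principal components of log2 CPM over the tested miRNA loci, with 1 point per library, coloured by diet and time and numbered by replicate; axes are component scores (no unit), with the share of variance. HFCF libraries at 3 months lie at 5.91 to 9.35 on the first component, and chow replicate 2 at 1 month lies at 7.23 on the second.

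The comparison at 1 month asked which miRNAs differed early on the diet. The clearest difference was a drop of the whole miR-183 cluster (Mir183, Mir96 and Mir182), made from 1 stretch of chromosome 6 and best known from sensory organs. Mir183 fell from 154 ± 45.4 CPM in chow to 33.1 ± 8.25 CPM in HFCF mice (log2 fold change -2.22 ± 0.33 SE, n = 3 per group, edgeR adjusted p = 0.00185). Mir182 fell from 399 ± 123 to 92.5 ± 25 CPM (-2.11 ± 0.30, adjusted p = 0.00185) and Mir96 from 45.7 ± 10.5 to 12.4 ± 4.27 CPM (-1.87 ± 0.29, adjusted p = 0.00185). All 3 HFCF libraries lay below all 3 chow libraries for each of them. The other miRNAs that fell come from the Dlk1-Dio3 locus of chromosome 12, an imprinted region whose miRNAs are expressed from the maternal allele. They were Mir341 (-2.37 ± 0.41, adjusted p = 0.00444, under 10 CPM in each group), Mir127 (-1.49 ± 0.36, 0.0381), Mir434 (-1.37 ± 0.32, 0.0381) and Mir136 (-1.25 ± 0.28, 0.0329).

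The cluster lies between annotated genes on the minus strand of chromosome 6 (mm10), with Mir182 at 30165918 to 30165992, Mir96 at 30169446 to 30169551 and Mir183 at 30169668 to 30169737. In the Dlk1-Dio3 region, Mir127 (109592832 to 109592928), Mir434 (109594506 to 109594599) and Mir136 (109595317 to 109595398) lie between genes and Mir341 (109611500 to 109611595) in an intron of the non-coding gene Rian.

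In all, 7 of 227 miRNAs fell and 0 rose at 1 month by edgeR, with 41 at an unadjusted p under 0.05. DESeq2 called 12, of which 2 were higher, and limma-voom called 5, all lower. The HFCF and chow libraries did not overlap for 18.9% of miRNAs, where chance gives 10%. With scaling that left out the most abundant miRNA, 1 of the 7 called was higher. The next smallest p-values did not pass: Mir137 (-1.37, adjusted p = 0.0627), Mir381 (-1.01, 0.0699) and Mir574 (0.49, 0.0714). All 3 passed with DESeq2 and without chow replicate 3, and Mir137 and Mir381 with library totals. They passed in 5, 3 and 7 of 23 alternatives, with adjusted p from 0.00872 to 0.273, 0.018 to 0.452 and 0.00872 to 0.204. Neither did Mir33, which lies in an intron of the sterol regulator Srebf2 (-0.93, 0.151). Mir375 had a value of -2.10 (0.165), and of -0.13 without chow replicate 2, with adjusted p from 0.0376 to 0.946 over its alternatives. Nor did Mir200b (-0.72, 0.201), Mir148a (0.26, 0.225) or the miR-378a locus AC116595.1 (0.31, 0.165) pass, the last passing only without chow replicate 3 or HFCF replicate 1 (0.0263 to 0.359 over its alternatives). The remaining miRNAs of interest also did not pass: Mir451 (0.38, adjusted p = 0.58), Mir132 (0.22, 0.808), Mir192 (0.19, 0.474), Mir223 (0.18, 0.699) and Mir142 (0.10, 0.849). The same held for Mir29a (0.08, 0.766), Mir21 (0.08, 0.84), Mir155 (0.08, 0.91), Mir27b (0.06, 0.836), Mir34a (0.04, 0.955) and Mir802 (-0.08, 0.886). Of these only Mir451 passed in an alternative, without chow replicate 1 (adjusted p = 0.00149, up to 0.837 over all), the library in which it was highest.

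Among the fixed lists, all 3 members of the miR-183 cluster fell, also when adjusted over the list alone (camera adjusted p = 2.57e-06; adjusted p = 0.169 with an estimated correlation; fry adjusted p = 0.00441). Of 17 measured Dlk1-Dio3 miRNAs, 4 fell, 0 rose and 13 did not pass. When adjusted over the list alone 11 fell (camera adjusted p = 2.38e-09; adjusted p = 0.372 with an estimated correlation). The chow libraries differed in this group. The mean centred log2 level of its members was 1.34 and 1.13 in replicates 1 and 2 and 0.27 in replicate 3, against 0.43, -0.03 and -0.44 in the HFCF libraries. The median log2 fold change of the 17 was -1.03. It was -0.751 without chow replicate 1 and -0.906 without chow replicate 2, with 1 of 17 passing by edgeR in each case, and -0.724 without HFCF replicate 3, with 0 passing. Without chow replicate 3 it was -1.25, with 10 passing. Without HFCF replicate 1 or 2 it was -1.3 and -0.841, with 2 passing in each case. The list of miRNAs reported lowered in fatty or fibrotic liver lay higher than other miRNAs (camera adjusted p = 0.0226, median 0.25). It had an adjusted p = 0.487 with an estimated correlation and 0.113 without HFCF replicate 3, and 0 of its 11 members passed in edgeR, also when adjusted over the list alone.

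No other list passed at 1 month. The 5 miR-200 family miRNAs of bile duct epithelium were all negative (median -0.72, camera adjusted p = 0.0552) and none passed. The chow library with high Mir200c is among those compared. The erythroid list had a median of 0.38 (0.0877), the mesenchymal list -0.53 (0.132), the leukocyte list 0.08 (0.9) and the hepatocyte list 0.11 (0.129). The lipid and sterol list had a median of 0.12 (0.0647), the list reported raised -0.17 (0.104, with 3 of 21 lower, the miR-183 cluster). Medians were 0.27 for the miR-29 family (0.129), 0.10 for let-7 (0.104), -0.10 for miR-17/92 (0.911) and -0.01 for the neuronal list (0.687). Single members stood for the endothelial (Mir126, 0.15), Sfmbt2 (-0.28), muscle (-0.27) and pancreas (Mir375, -2.10) lists.

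Leaving out chow replicate 3 at 1 month moved the count of changed miRNAs from 7 to 24. It was 3 without HFCF replicate 3 of that time and 4 without each of chow replicate 2 at 1 month, chow replicates 2 and 3 at 3 months and HFCF replicate 3 at 3 months. Mir183, Mir182 and Mir96 passed in all 23 alternatives (adjusted p up to 0.0394). Mir341 was lost without HFCF replicate 3 and with all genes in 1 fit (adjusted p up to 0.0613). Mir127 was lost in 15 of 23 alternatives, Mir434 in 11 and Mir136 in 9, with adjusted p up to 0.241, 0.248 and 0.224. All 3 were lost without chow replicate 1, chow replicate 2 or HFCF replicate 3 at 1 month, and without chow replicate 2, chow replicate 3 or HFCF replicate 3 at 3 months. Mir127 and Mir434 were also lost without HFCF replicate 1 at 1 month, and Mir127 and Mir136 without HFCF replicate 2 at 1 month. Mir434 was lost without HFCF replicate 2 at 3 months as well. Libraries of 3 months are not among those compared here and enter only through the filter, the scaling and the shared spread. Losses without them thus show calls near the threshold.

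The comparison at 3 months asked which miRNAs differed after longer feeding. The largest increases were of miRNAs that were scarce in chow liver. Mir582, in an intron of the phosphodiesterase gene Pde4d, rose from 2.14 ± 1.33 to 74.8 ± 49.0 CPM (log2 fold change 5.09 ± 0.69 SE, n = 3 per group, edgeR adjusted p = 0.000392). Mir205, an epithelial miRNA, rose from 5.77 ± 1.99 to 88.6 ± 51.4 CPM (3.98 ± 0.51, adjusted p = 0.000287). Mir149, in an intron of the heparan sulfate proteoglycan gene Gpc1, rose from 50.8 ± 5.50 to 278.5 ± 26.7 CPM (2.46 ± 0.29, 0.000287). The immune-cell miRNA Mir155 (1.80 ± 0.36, 0.00435), the p53-induced Mir34a (1.67 ± 0.34, 0.00435) and the myeloid miRNA Mir223 (1.16 ± 0.19, 0.00161) rose as well. On the other side, Mir33 fell from 28.4 ± 7.09 to 8.12 ± 2.25 CPM (-1.80 ± 0.32, 0.00204), and 12 of 17 miRNAs of the Dlk1-Dio3 cluster fell (camera adjusted p = 8.95e-08 for the list; adjusted p = 0.68 with an estimated correlation).

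**Figure D2:**
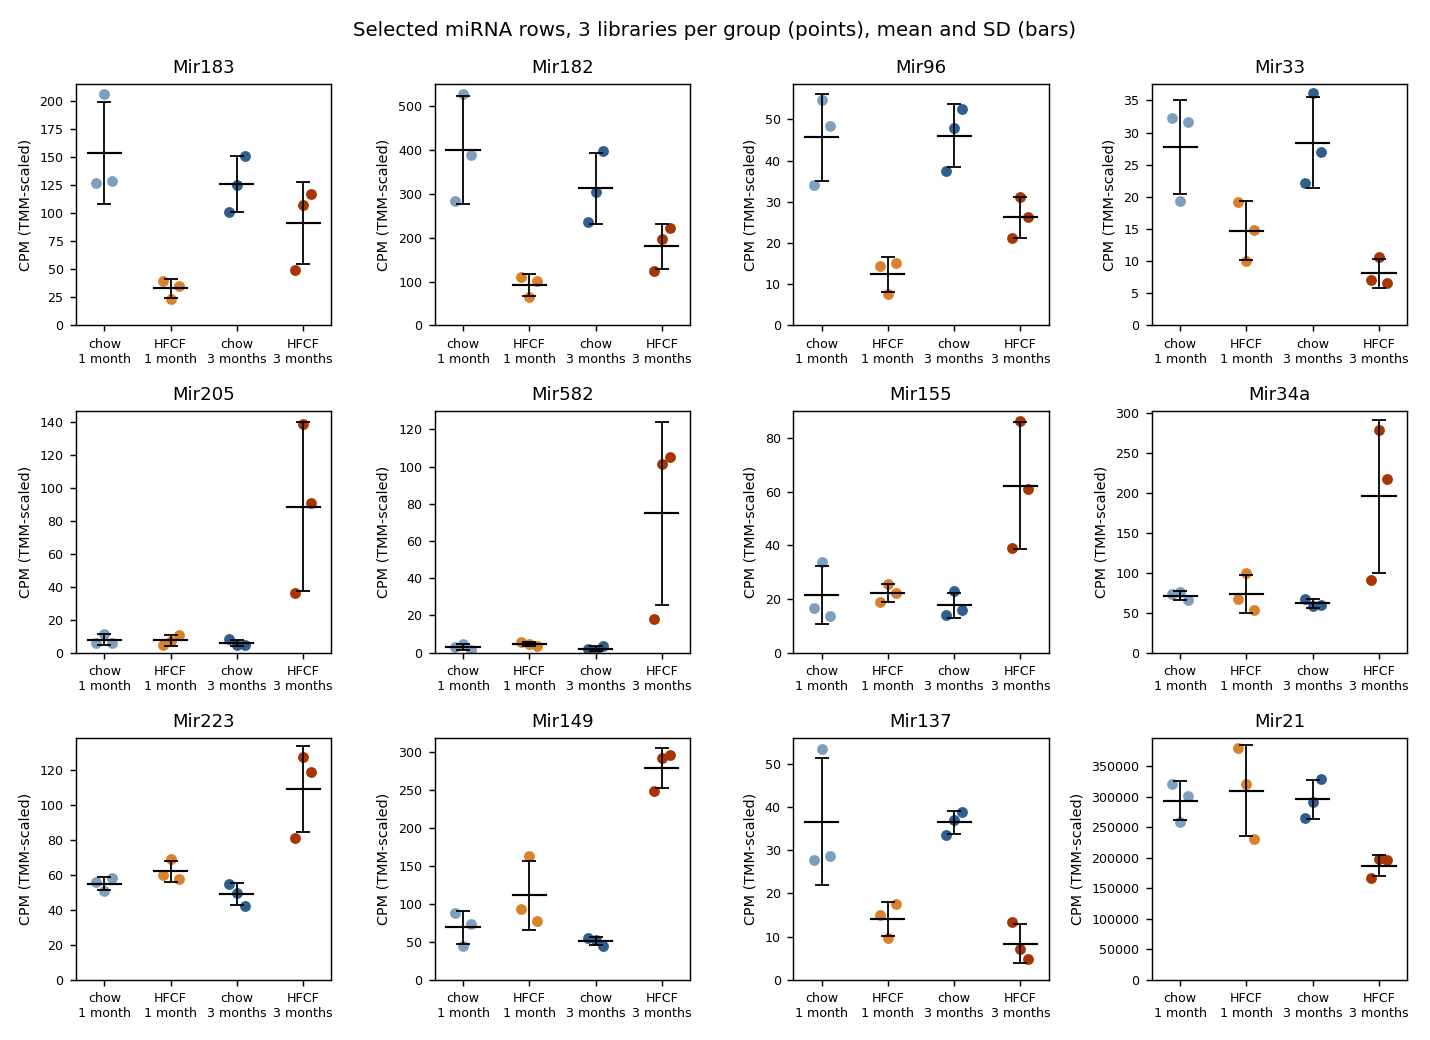
Levels of 12 named miRNAs in TMM-scaled CPM (vertical axes, from 0) by diet and time (horizontal axes); points are the 3 libraries of a group and bars the mean and SD. Mir183, Mir182 and Mir96 are lowest in HFCF mice at 1 month, and Mir205, Mir582, Mir155, Mir34a, Mir223 and Mir149 are highest in HFCF mice at 3 months, where 1 of 3 libraries lies lower for Mir582 (18.3 CPM against 101 and 105).

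By edgeR, 52 of 227 miRNAs changed at 3 months, 20 higher and 32 lower, and 80 had an unadjusted p under 0.05. Of the 52 changed miRNAs, 31 had more than a 2-fold change. Libraries of the diets did not overlap for 39.2% of miRNAs, where chance gives 10%. With library totals in place of TMM the split was 59 higher and 18 lower of 77, and with all genes of the table in 1 fit 19 higher and 10 lower of 29. The other large increases were of Mir676 in an intron of Eda (1.22 ± 0.15, adjusted p = 0.000287), Mir132 (1.18 ± 0.33, 0.0202), Mir802, a miRNA linked to obesity in mouse liver (1.10 ± 0.27, 0.0125), and Mir181b-2 (1.05 ± 0.29, 0.0188). They also included Mir335 in an intron of the imprinted gene Mest (0.96 ± 0.16, 0.00161) and the leukocyte miRNA Mir342 in an intron of Evl (0.95 ± 0.21, 0.00849). The largest decreases outside the Dlk1-Dio3 cluster were of Mir137, a neuronal miRNA (-2.15 ± 0.38, 0.00199), Mir33, Mir592 within Grm8 (-1.79 ± 0.46, 0.0169) and the X-linked Mir741 (-1.70 ± 0.39, 0.00962).

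On mm10, Mir582 lies at 109324744 to 109324824 of chromosome 13, Mir205 at 193507463 to 193507530 of chromosome 1 in an exon of the non-coding gene 4631405K08Rik, and Mir149 at 92850378 to 92850443 of chromosome 1. Mir155 starts at 84714140 of chromosome 16 in an exon of its host transcript Mir155hg, Mir34a lies at 150068454 to 150068555 of chromosome 4 between genes, Mir33 at 82198122 to 82198190 of chromosome 15, and Mir21 at 86584067 to 86584158 of chromosome 11 in an exon annotated to Vmp1.

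Mir21, often studied in liver injury, fell from 295600 ± 32090 to 187000 ± 16940 CPM (-0.66 ± 0.16, adjusted p = 0.0135). Its change was -0.40 (0.0379) with library totals, and its call was lost with all genes in 1 fit (0.499, the highest of its alternatives) and without chow replicate 3 at 3 months (0.0617). Mir29a, an antifibrotic miRNA, fell by 0.37 ± 0.12 on the log2 scale (0.0369) and Mir96 by 0.81 ± 0.27 (0.0477). Under library totals their values were -0.12 (0.456) and -0.55 (0.155). Each call was lost in 11 of 23 alternatives (adjusted p up to 0.872 and 0.407), among them without chow replicate 3 at 1 month, any chow library at 3 months, or HFCF replicate 2 or 3 at 3 months. Mir96 was also lost without HFCF replicate 1 at 3 months (0.122). The miR-378a locus AC116595.1 (0.23, 0.155) and Mir148a (0.10, 0.568) did not pass, but did with library totals (0.49 and 0.34, adjusted p = 0.00503 and 0.0235). Other miRNAs of interest did not pass: Mir182 (-0.79, 0.0674), Mir27b (-0.25, 0.096), Mir192 (-0.26, 0.167), Mir200b (0.50, 0.271) and Mir183 (-0.46, 0.325). Mir142 (0.28, 0.411), Mir451 (0.21, 0.649) and Mir375 (0.16, 0.912) did not pass either. Mir182 passed in 5 of 23 alternatives (adjusted p from 0.0246 to 0.409), with DESeq2, with only the libraries compared, and without chow replicate 1, chow replicate 2 or HFCF replicate 2 at 1 month. Mir27b passed in 8 (0.012 to 0.992), with DESeq2 and its size factors, with scaling without the most abundant miRNA, with no filter, and without chow replicate 2 or any HFCF library at 1 month. Its value was 0.01 with library totals. Mir192 passed without chow replicate 2 at 1 month (0.0129, with 0.998 as the highest).

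All 17 Dlk1-Dio3 miRNAs had a negative log2 fold change at 3 months (median -1.56). Of them 12 fell, 0 rose and 5 did not pass, and 17 fell when adjusted over the list alone (camera adjusted p = 8.95e-08, fry 0.0374; adjusted p = 0.68 with an estimated correlation). Mir381 (-1.71 ± 0.30, adjusted p = 0.00199), Mir411 (-1.62 ± 0.30, 0.00264) and Mir136 (-1.60 ± 0.31, 0.00343) passed in all 23 alternatives. Mir541 (-1.58 ± 0.42, 0.0174), Mir300 (-1.56 ± 0.41, 0.0172), Mir434 (-1.39 ± 0.34, 0.0135), Mir127 (-1.36 ± 0.37, 0.0188) and Mir379 (-1.29 ± 0.33, 0.0169) also fell. The mean centred log2 level of the group was -1.14, -1.17 and -1.06 in the HFCF libraries and 0.44, 0.01 and 0.22 in the chow libraries at 3 months. With 1 library of that time left out the median was -1.4 to -1.69 and 3 to 12 of the 17 passed. There were 6, 3, 7 and 5 without chow replicate 1, chow replicate 3, HFCF replicate 2 and HFCF replicate 3.

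**Figure D3:**
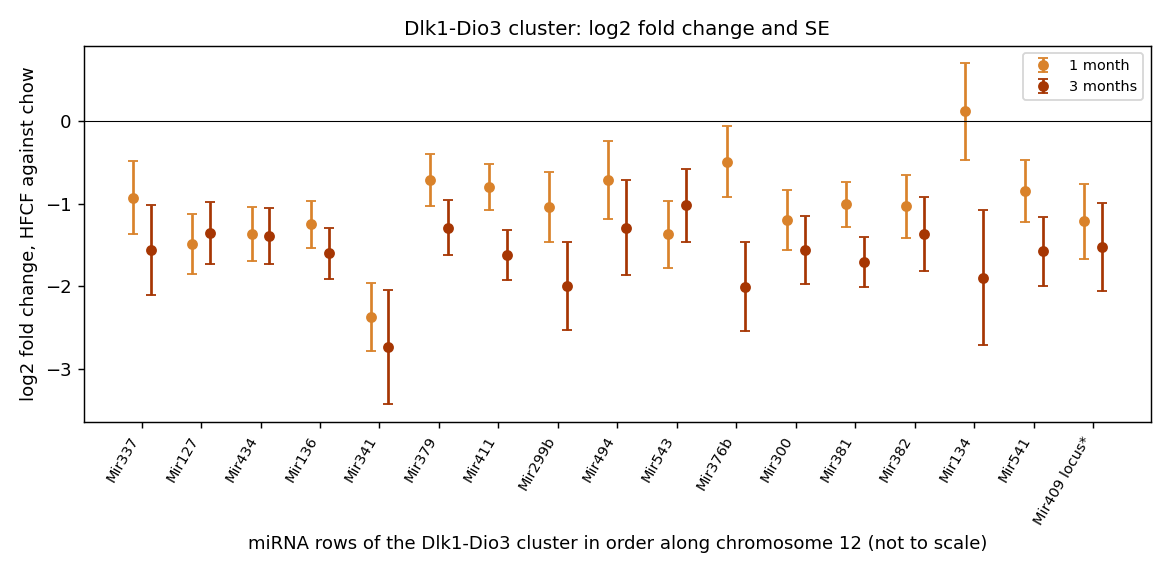
Log2 fold change of HFCF against chow (vertical axis) for the 17 measured miRNAs of the Dlk1-Dio3 cluster in their order along chromosome 12 (horizontal axis, not to scale), at 1 month and 3 months; bars are SE and the locus marked with an asterisk was assigned by its coordinates. All 17 lie below 0 at 3 months, with a median of -1.56, against a median of -1.03 at 1 month.

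The list of miRNAs reported raised in fatty or fibrotic liver lay higher at 3 months (camera adjusted p = 0.0406). It had an adjusted p = 0.68 with an estimated correlation and a fry adjusted p = 0.111. Of its 21 members 7 rose, 2 fell and 12 did not pass, with 8 and 3 when adjusted over the list alone. The call was lost at the filter of 10 CPM (0.0872), without chow replicate 1 (0.0843) or 3 (0.0552) and without HFCF replicate 2 (0.141) or 3 (0.102) of that time. HFCF replicate 1 did not share the rise. The mean centred log2 level of the list was -0.135 in it, within the chow libraries (-0.256, 0.0407 and -0.0643), and 0.598 and 0.485 in HFCF replicates 2 and 3. Without it the adjusted p was 0.0023. The mesenchymal list, which shares Mir214 with this one, split the same way, with -0.406 in HFCF replicate 1 against 0.298 and 0.343. Those that rose were Mir155, Mir132, Mir34a, Mir223, Mir181b-2, Mir222 (0.87 ± 0.14, edgeR adjusted p = 0.00171) and Mir221 (0.56 ± 0.12, 0.0062), and those that fell were Mir21 and Mir96. Of the list reported lowered, 1 of 11 rose (Mir802), 2 fell (Mir29a and Mir30c-2) and 8 did not pass (camera adjusted p = 0.631).

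Markers of cell types moved unevenly at 3 months. Of 7 leukocyte miRNAs, 3 rose (Mir155, Mir223 and Mir342), 1 fell (Mir511, -0.60 ± 0.18, edgeR adjusted p = 0.0307) and 3 did not pass, with 3 and 2 when adjusted over the list alone (camera adjusted p = 0.228). Of 7 hepatocyte miRNA loci, Mir802 rose, Mir101a (-0.56, 0.0202) and Mir101b (-0.54, 0.0202) fell and 4 did not pass (0.508). None of the 4 mesenchymal (0.755), 5 miR-200 family (0.799) or 3 erythroid (0.801) miRNAs passed, and endothelial Mir126 had a log2 fold change of -0.03. In the lipid and sterol list 4 of 16 rose (Mir34a, Mir223, Mir103-2 and Mir185), 2 fell (Mir33 and Mir30c-2) and 10 did not pass (0.228). When adjusted over the list alone 5 rose and 2 fell. The let-7 family had 2 of 12 higher and 1 lower (camera adjusted p = 0.214; fry adjusted p = 0.0374). A single member each was lower in the miR-29 family (of 4, 0.269), the miR-183 cluster (of 3, 0.214), miR-17/92 (of 11, 0.486) and the neuronal list (of 3, 0.801). The neuronal median was 0.27 while its mean, -0.44, and its test pointed down. The single Sfmbt2 (0.24), muscle (0.30) and pancreas (0.16) members did not pass.

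Counts at 3 months moved when single libraries of that time were left out. There were 20 miRNAs changed without chow replicate 3, 26 without HFCF replicate 3 and 32 without HFCF replicate 2. A lower count is expected from a lost replicate alone, while 70 changed without HFCF replicate 1. Under every alternative 18 of the 52 passed, 12 higher and 6 lower, among them Mir582, Mir205, Mir149, Mir155, Mir34a, Mir223, Mir802, Mir137 and Mir33. Without chow replicate 3 at 3 months Mir342, Mir741, Mir132, Mir181b-2, Mir127, Mir379, Mir300, Mir434 and Mir541 were lost, and without HFCF replicate 3 these except Mir342 and Mir300, together with Mir592. Without chow replicate 1 Mir132, Mir181b-2, Mir127, Mir379, Mir300 and Mir541 were lost. Without HFCF replicate 2 Mir132, Mir181b-2, Mir127, Mir300, Mir541 and Mir592 were lost, and without chow replicate 2 Mir592. The highest adjusted p over all alternatives was 0.0529 for Mir342, 0.0606 for Mir741, 0.0869 for Mir132, 0.0944 for Mir181b-2 and 0.103 for Mir592. It was 0.102 for Mir127, 0.0862 for Mir379, 0.0654 for Mir300, 0.0575 for Mir434 and 0.0892 for Mir541.

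Comparing the 2 times showed partial overlap of the diet effects. Mir341, Mir96, Mir127, Mir434 and Mir136 were lower at both times, 5 miRNAs where independent lists of these sizes share 0.987. All of them except Mir96 are neighbours in the Dlk1-Dio3 region. They are not independent calls, so the value of 0.987 makes the overlap look larger than it is. No miRNA was higher at both times, since edgeR called 0 higher at 1 month. Across the 227 miRNAs, which are not independent replicates, the log2 fold changes at the 2 times correlated with Pearson r = 0.465 and Spearman rho = 0.386, and 64.8% had the same sign. Of the 52 miRNAs changed at 3 months, 42 had the same sign at 1 month, with medians at 1 month of 0.16 for those higher and -0.60 for those lower. The number shared was 0 without chow replicate 3 or HFCF replicate 3 at 3 months, 1 without HFCF replicate 3 at 1 month or chow replicate 2 at 3 months, and 2 without HFCF replicate 2 at 3 months. It was 3 without chow replicate 2 or HFCF replicate 1 at 1 month or chow replicate 1 at 3 months, and 10 without chow replicate 3 at 1 month.

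**Figure D4:**
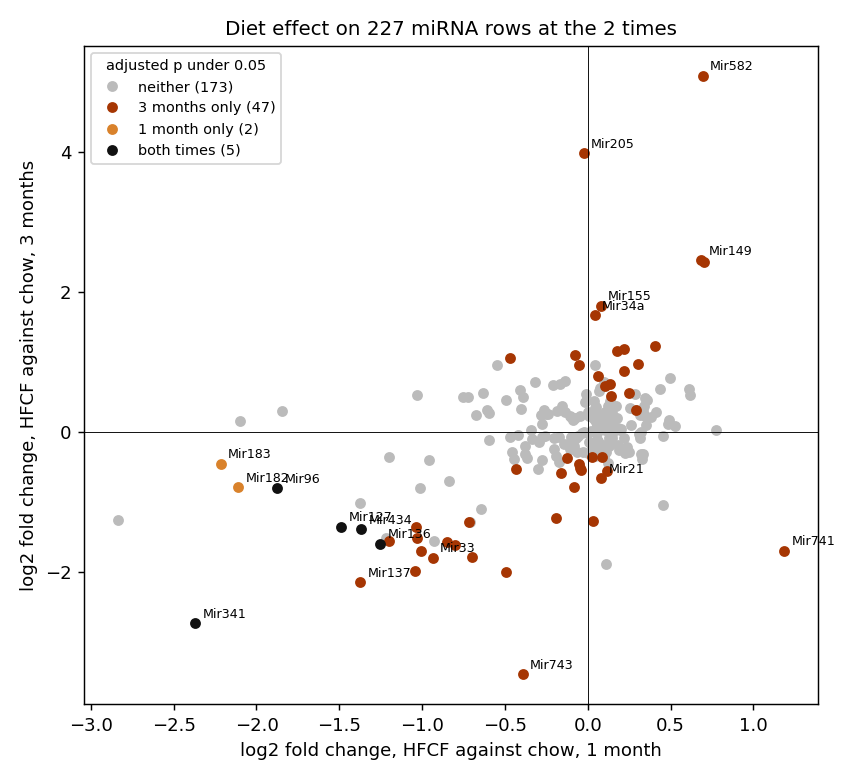
Log2 fold change of HFCF against chow at 1 month (horizontal axis) and at 3 months (vertical axis) for the 227 tested miRNAs, 1 point each, coloured by the times at which the edgeR adjusted p was under 0.05. Mir341, Mir96, Mir127, Mir434 and Mir136 passed at both times, and Mir582, Mir205 and Mir149 lie far up at 3 months.

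Tested directly, the diet effect differed between the times for 2 miRNAs. Mir205 rose with the diet by 4.01 ± 0.75 more on the log2 scale at 3 months than at 1 month (n = 3 per group, edgeR adjusted p = 0.0326). Mir741 had a log2 difference of -2.89 ± 0.60 (0.0436), from 2.90 ± 1.30 CPM in chow and 6.34 ± 2.17 CPM in HFCF mice at 1 month to 13.7 ± 4.71 and 4.29 ± 1.5 CPM at 3 months. Mir149 (1.77 ± 0.40, 0.0515), Mir582 (4.4 ± 1.11, 0.082) and Mir183 (1.76 ± 0.45, 0.082) did not pass in edgeR. With DESeq2 all 3 passed (adjusted p = 0.000874, 0.000473 and 0.0062), as they did with library totals and without HFCF replicate 1 at 3 months (0.0232, 0.00125 and 0.00765). Mir149 also passed with DESeq2 size factors (0.0499) and without chow replicate 2 (0.0307) or HFCF replicate 2 (0.0148) at 1 month. Over their 22 alternatives the highest adjusted p were 0.385, 0.397 and 0.182. Whether the diet effect on Mir183 differed between the times thus depended on the test, the scaling and HFCF replicate 1 at 3 months. An unadjusted p under 0.05 was found for 43 miRNAs.

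As a group the miRNAs reported raised in fatty or fibrotic liver had a higher diet effect at 3 months than at 1 month (camera adjusted p = 7.12e-06; adjusted p = 0.551 with an estimated correlation). Of its 21 members 0 passed in edgeR, and 9 were higher and 1 lower when adjusted over the list alone. As noted above, HFCF replicate 1 at 3 months did not share the rise of this list at that time. The miR-183 cluster, which is part of that list, had 0 of 3 passing and 3 higher over the list alone (camera adjusted p = 0.013; adjusted p = 0.551 with an estimated correlation). The miR-29 family had a lower diet effect at 3 months, with 0 of 4 passing and 2 lower over the list alone (camera adjusted p = 0.0302; adjusted p = 0.551 with an estimated correlation). The list reported lowered (0 of 11 passing, also over the list alone) and the Dlk1-Dio3 cluster (0 of 17 passing, also over the list alone) each had a camera adjusted p = 0.0302. These became an adjusted p = 0.596 and 0.636 with an estimated correlation.

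The calls of the 3 lists with a lower effect depended on single libraries. Without chow replicate 2 at 1 month, the library high in Mir375, the Dlk1-Dio3 cluster (0.0525), the miR-29 family (0.0666) and the list reported lowered (0.0666) were lost. The list reported lowered was also lost without HFCF replicate 3 at 1 month (0.0894). The miR-29 family was lost without chow replicate 3 (0.058), HFCF replicate 1 (0.0517) or HFCF replicate 3 (0.0894) at 1 month and without chow replicate 2 (0.0563) or HFCF replicate 2 (0.067) at 3 months. The Dlk1-Dio3 cluster was lost at the filter of 10 CPM (0.0628) and without chow replicate 3 (0.767), HFCF replicate 1 (0.533) or HFCF replicate 2 (0.155) at 1 month. It was also lost without chow replicate 1 (0.114), HFCF replicate 1 (0.0908) or HFCF replicate 2 (0.0913) at 3 months.

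The single-miRNA counts moved widely. Limma-voom called 0, DESeq2 called 19 (14 higher, 5 lower) and library totals gave 26 (25 higher, 1 lower). Leaving out HFCF replicate 1 at 3 months gave 28 and HFCF replicate 2 at 1 month 1. Leaving out chow replicate 3 or HFCF replicate 1 at 1 month, any chow library at 3 months or HFCF replicate 2 or 3 at 3 months gave 0. Mir205 was lost in 11 of 22 alternatives (adjusted p up to 0.152), also without chow replicate 2 or HFCF replicate 2 at 1 month. Mir741 was lost in 12 (up to 0.167), also without chow replicate 1 or HFCF replicate 2 or 3 at 1 month.

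The comparison of times in chow mice asked what changed with age and time alone, and 1 miRNA did. Mir741, one of a group of X-linked miRNAs, rose by 2.29 ± 0.43 on the log2 scale from 1 month to 3 months (n = 3 per group, edgeR adjusted p = 0.0377). Next came Mir341 (-1.85 ± 0.41, 0.0732), Mir881 (1.22 ± 0.38, 0.391), Mir486 (-1.05 ± 0.34, 0.391) and Mir127 (-1.04 ± 0.35, 0.391), none of which passed. Mir341, Mir486 and Mir127 passed without chow replicate 3 at 1 month (0.0395 each), and Mir881 with all genes in 1 fit (0.0338), while their highest adjusted p were 0.585, 0.724, 0.786 and 0.724. All 17 Dlk1-Dio3 miRNAs were negative (median -0.75), with 0 passing and 1 when adjusted over the list alone (camera adjusted p = 6.96e-09; adjusted p = 0.824 with an estimated correlation). The 2 chow libraries with high levels of this group at 1 month, replicates 1 and 2, are in this comparison. The 3 erythroid miRNAs also lay lower as a group (median -0.85, 0 passing, 2 over the list alone; camera adjusted p = 0.0406; adjusted p = 0.9 with an estimated correlation). The call was lost without chow replicate 1 at 1 month (0.338), the library highest in Mir451. It was also lost at the filter of 10 CPM (0.0596) and without chow replicate 1 (0.121) or 2 (0.103) or HFCF replicate 1 (0.0893), 2 (0.0592) or 3 (0.0748) at 3 months.

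There were 23 miRNAs at an unadjusted p under 0.05 in chow, and DESeq2 also called 1 and limma-voom 0. The count was 8 without chow replicate 3 at 1 month and 0 without chow replicate 1 or HFCF replicate 3 at 1 month, any chow library at 3 months or HFCF replicate 2 or 3 at 3 months. Mir741 was lost in 10 of 23 alternatives (highest adjusted p 0.294), those 7 libraries included.

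In HFCF mice, where time on the diet is added to age, 36 miRNAs changed between 1 and 3 months, 19 higher and 17 lower, with 76 at an unadjusted p under 0.05. Mir205 (3.55 ± 0.48, n = 3 per group, edgeR adjusted p = 0.00137) and Mir582 (3.98 ± 0.60, 0.00219) rose most clearly, followed by Mir676 (0.90 ± 0.15, 0.00387) and Mir335 (0.83 ± 0.16, 0.00846). Mir411 of the Dlk1-Dio3 cluster fell (-1.53 ± 0.30, 0.00997). All 3 miRNAs of the miR-183 cluster rose from their low level at 1 month, and all 3 erythroid miRNAs fell.

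Of the lists, 6 passed in camera, each with an adjusted p = 0.38 with an estimated correlation. In the list reported raised 10 of 21 rose and 1 fell, the same numbers over the list alone (camera adjusted p = 3.72e-05). Its level rose in HFCF replicates 2 and 3 at 3 months (mean centred log2 level 0.598 and 0.485), while replicate 1 (-0.135) lay near the HFCF libraries at 1 month (-0.161, -0.411 and -0.348). The mesenchymal list was likewise low in replicate 1 (-0.406) and higher in replicates 2 and 3 (0.298 and 0.343), against 0.0216, -0.418 and -0.211 at 1 month. The miR-183 cluster (3 of 3 higher) and the erythroid list (3 of 3 lower) each had a camera adjusted p = 0.0183. Of the Dlk1-Dio3 miRNAs 7 of 17 fell, and 16 when adjusted over the list alone (2.65e-07). The miR-29 family lay lower with 0 of 4 passing and 3 lower over the list alone (median -0.38, 0.0428). The list reported lowered also lay lower with 1 of 11 higher and 1 lower, the same over the list alone (median -0.36, 0.0183). Replicate 1 did not share these falls either, with 0.142 for the miR-29 family and 0.119 for the list reported lowered, against -0.37 and -0.515, and -0.146 and -0.261, in replicates 2 and 3. The 2 medians are close in size to the shift of 0.35 that library totals give to all miRNAs.

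With library totals 83 miRNAs changed over time in HFCF mice, 73 higher and 10 lower, and with all genes in 1 fit 22, of which 20 were higher. The count was 5 without HFCF replicate 3, 6 without HFCF replicate 2 and 57 without HFCF replicate 1 at 3 months, and 10 without HFCF replicate 1 at 1 month. Mir205, Mir582, Mir676 and Mir335 passed in all 23 alternatives, and Mir411 was lost without HFCF replicate 3 at 3 months (adjusted p = 0.0512, the highest of its alternatives). The call of the list reported lowered was lost without HFCF replicate 3 at 1 month (0.128) or at 3 months (0.0714). That of the miR-29 family was lost at the filter of 10 CPM (0.0554) and without chow replicate 1 (0.0506), 2 (0.0533) or 3 (0.0649) or HFCF replicate 1 (0.0508) or 3 (0.153) at 1 month. It was also lost without HFCF replicate 2 (0.0651) or 3 (0.0952) at 3 months.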

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

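Of the tests in this part, those of single explanations for the 3 patterns were chosen after the results were seen; the counts over other splits of the libraries were planned. The SE of a difference between lists is built from the mean SE of each list's members, as if the members of a list moved together and the lists did not.

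The diet effect differed between the times for Mir205, by 4.01 on the log2 scale, and for Mir741, by -2.89. It also differed for the list reported raised in fatty or fibrotic liver (camera adjusted p = 7.12e-06), the miR-183 cluster (0.013), the miR-29 family (0.0302), the list reported lowered (0.0302) and the Dlk1-Dio3 cluster (0.0302). None of these held with an estimated correlation, which gave an adjusted p from 0.551 to 0.636. Of 100 splits of the libraries within each time, drawn from 200, 10 gave at least the 2 miRNAs of the real split, so chance is not excluded for that count. The highest other split gave 48. It keeps all chow and HFCF libraries of a time together and exchanges the diets at 3 months, so it adds the 2 diet effects where the real split takes their difference. Its many calls thus point to a structure of the samples that is the diet effect reported above, and are no further evidence for it. The other splits with more than 2 miRNAs also kept the diets of 3 months whole.

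The other comparisons have 10 splits of 6 libraries each, too few for a share under 0.05. The real count was 7 and the highest other 1 for diet at 1 month (1 of 10 splits as large), 52 and 0 for diet at 3 months (1 of 10), 1 and 4 for time in chow (2 of 10) and 36 and 1 for time in HFCF mice (1 of 10). The split of chow libraries that gave 4 set replicates 1 and 2 of 1 month, the libraries with high Dlk1-Dio3 levels, with replicate 1 of 3 months.

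Outside the miRNAs, fragments of 26 of 1552 protein-coding genes changed with diet at 1 month and of 38 at 3 months by edgeR, and 1 of 257 snoRNA and scaRNA genes changed at 3 months (Snord123, 2.07 ± 0.32 SE, adjusted p = 0.0035), named after its value was seen.

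The drop of Mir183, Mir182 and Mir96 at 1 month was weighed against a single unusual chow library, replicate 2. Without it the median of the 3 was -1.80 and all 3 passed (highest adjusted p 0.00911), which argues against that library as the whole cause. Fewer epithelial cells in HFCF mice would lower the miR-200 family alike. Its median lay 1.39 above that of the cluster (SE 0.49), though all 5 members were negative (median -0.72). Since the cluster was picked because it fell, this gap cannot decide the question. A candidate explanation on the biological side is lower activity of the sterol regulator SREBP2, a hypothesis; the fragments of sterol synthesis genes gave an adjusted p = 0.149 with an estimated correlation (median -0.59), which leaves it open. The diet itself acting on the cluster stays open, as untested.

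The Dlk1-Dio3 miRNAs lay lower with the diet at both times, with medians of -1.03 and -1.56. At 3 months the median was -1.31 with library totals (11 lower), which argues against the choice of TMM over library totals as the cause. The mesenchymal miRNAs lay 1.78 above the cluster (SE 0.547), with a median of 0.22 and none of 4 passing. Their mean centred log2 level was -0.406 in HFCF replicate 1, against 0.298 and 0.343 in replicates 2 and 3. Since the cluster was picked because it fell, the gap of 1.78 cannot decide on fewer mesenchymal cells. At 1 month the Dlk1-Dio3 levels were high in chow replicates 1 and 2. Without replicate 1 the median was -0.751 and without replicate 2 -0.906, with 1 of 17 passing in each case in place of 4. The list stayed lower in camera at the preset correlation (adjusted p up to 3.11e-05 with 1 library left out), while an estimated correlation gave 0.372 with all libraries. This leaves open whether the part at 1 month rests on either library, since most single calls ended while the median stayed negative. High levels in both together also stay open: leaving out libraries noticed for these levels shrinks the difference by design. With 1 library left out at 3 months 3 to 12 of 17 passed, with medians of -1.4 to -1.69. A direct effect of the diet on this imprinted region stays a hypothesis.

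The rise of Mir155, Mir223 and Mir342 at 3 months was weighed against shifts in cell content. More leukocytes of every kind would raise the whole list, but Mir511, a macrophage miRNA, fell (-0.597). This is a single miRNA whose call did not hold under every alternative, so it does not decide the question. Fewer hepatocytes would raise all other cell types alike. Endothelial Mir126 lay -1.19 (SE 0.277) and the mesenchymal median -0.938 (SE 0.385) from the median of the 3. Since the 3 were picked because they rose, these gaps cannot decide the question. The median of the whole leukocyte list was 0.45, against 0.22 for the mesenchymal list and -0.03 for Mir126. Fragments of 5 of 29 hepatocyte genes fell and 0 rose (camera adjusted p = 2.13e-05, and 0.148 with an estimated correlation). The hepatocyte miRNA list did not pass (camera adjusted p = 0.508), so fewer hepatocytes remain open. The leukocyte mRNA fragments had an adjusted p = 0.371 with an estimated correlation over 4 genes, so a hypothesis of more cells of some leukocyte types remains open, as does induction within resident cells.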

How the results depend on the processing

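In this part the setting without chow replicates 1 and 2 at 1 month was chosen after seeing the data; all other settings were planned. That setting leaves 1 chow library at 1 month, with the spread taken from the other groups, so a lower count in it is expected from the lost replicates and does not show that a result depends on those 2 libraries. No named miRNA or list that was called changed direction under an alternative. The balance of higher and lower calls did for diet at 3 months, with 38.5% of calls higher, 76.6% with library totals and 65.5% with all genes in 1 fit. It also turned, among fewer calls, without chow replicate 3 (60% higher) or HFCF replicate 3 (57.7%) at 3 months. Leaving out any other single library gave 32.3% to 50%. The cause was not tested for any of the moves below, except that the settings with fewer libraries or another threshold differ by construction. For diet at 1 month (7 miRNAs), all genes in 1 fit gave 3, DESeq2 12 and only the libraries compared 4, and leaving out 1 library gave 3 to 24 (3 without HFCF replicate 3 and 24 without chow replicate 3, both at 1 month). For diet at 3 months (52), all genes in 1 fit gave 29, and leaving out 1 library 20 to 70 (20 without chow replicate 3 and 70 without HFCF replicate 1 at 3 months; 26 and 32 without HFCF replicates 3 and 2). For the difference of diet effects (2), library totals gave 26, all genes in 1 fit 1, the stricter filter 1, DESeq2 19, limma-voom 0, an adjusted p under 0.1 gave 9, the setting without chow replicates 1 and 2 at 1 month 0, and leaving out 1 library 0 to 28 (28 without HFCF replicate 1 at 3 months). For time in chow (1), all genes in 1 fit gave 2, limma-voom 0, only the libraries compared 0, an adjusted p under 0.1 gave 2, the setting without chow replicates 1 and 2 gave 0, and leaving out 1 library 0 to 8 (8 without chow replicate 3 at 1 month). For time in HFCF mice (36), library totals gave 83, all genes in 1 fit 22, and leaving out 1 library 5 to 57 (5 without HFCF replicate 3 and 57 without HFCF replicate 1 at 3 months). The miRNAs shared by both times (5) were 2 with the stricter filter, 8 with DESeq2, 3 with limma-voom, 8 at an adjusted p under 0.1 and 0 to 10 with 1 library left out. At an unadjusted p under 0.05 edgeR had 43 miRNAs for the difference and 23 for time in chow.

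Lists called fell to 0 with an estimated correlation in every comparison. Of 3 called at 1 month fry called 1, and leaving out 1 library gave 3 to 8 (8, 6 and 5 without chow replicate 1, chow replicate 3 and HFCF replicate 1 at 1 month). Of 2 at 3 months the stricter filter called 1 and leaving out 1 library 1 to 2 (1 without chow replicate 1 or 3 or HFCF replicate 2 or 3 at 3 months). Of 5 for the difference fry called 0 and leaving out 1 library gave 2 to 8 (8 and 2 without chow replicates 1 and 2 at 1 month, 3 without HFCF replicate 3 at 1 month or HFCF replicate 2 at 3 months). Of 2 for time in chow the stricter filter called 1, fry 0 and leaving out 1 library 1 to 4 (4 without chow replicate 1 at 1 month, 1 without chow replicate 1 or 2 or any HFCF library at 3 months). Of 6 for time in HFCF mice leaving out 1 library gave 4 to 8. The difference in miRNA share between diets was 3.88 points at 1 month (1.12 to 6.32 with 1 library left out) and 0.38 points at 3 months (-2.03 to 2.21, so its sign turned without HFCF replicate 2 or chow replicate 1).

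The replicate number as a block gave 7, 48, 3, 0 and 31 miRNAs in the 5 comparisons, in the order above, and 4 shared. Whether the numbers mark a structure shared between groups stays open. Of 18 same-numbered pairs, 5 deviated together with a correlation over 0.1 (range -0.222 to 0.39). Among libraries of other groups, 7 of 12 libraries correlated best with one of their own number. Neither count was tested against chance. Among single named miRNAs and lists, 1844 values under an alternative kept their side of the threshold, 197 lost it and 51 gained it. The alternatives for normalized values were not run, since the table held counts, and the difference of diet effects uses all libraries, so a fit of only the libraries compared does not apply to it. Some tested miRNAs were scarce: Mir341, Mir743 and Mir1247 stayed under 10 CPM in both diets at 3 months. How far depth limited their tests was not examined.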

Other observations

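In this part all genes were named, and the lists of protein-coding genes and the X-linked group formed, after miRNA results were seen; the lists were written before the values of their genes. The table also held fragments of longer transcripts, in few counts each. At 1 month fragments of the desaturase gene Scd1 (log2 fold change 1.60 ± 0.28 SE, n = 3 per group, edgeR adjusted p = 0.00413), the peroxisomal enzyme gene Ehhadh (1.07 ± 0.21, 0.00188), the fatty acid binding protein gene Fabp1 (1.02 ± 0.23, 0.0071) and the receptor gene Ppara (1.15 ± 0.27, 0.00881) rose. Lpin1 (-1.22 ± 0.25, 0.00402) and Cyp3a11 (-1.37 ± 0.28, 0.0071) fell. At 3 months Scd1 rose by 3.36 ± 0.30 (1.48e-07), Cd36, a fatty acid transporter, by 1.85 ± 0.34 (0.000256) and Car3 by 2.61 ± 0.30 (8.67e-09). Genes that fell at 3 months included Cps1 (-1.45 ± 0.20, 4.05e-07), Got1 (-1.75 ± 0.31, 0.00013), Tat (-1.19 ± 0.23, 0.000627), Hal (-1.59 ± 0.32, 0.000884) and Arg1 (-0.91 ± 0.23, 0.0141). In all 15 genes rose and 11 fell at 1 month, and 15 rose and 23 fell at 3 months. For the difference of diet effects 0 of 1552 passed by edgeR, the only tool run on these genes, with 149 at an unadjusted p under 0.05.

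At 1 month 2 of 4 matrix genes, Col14a1 (1.51 ± 0.34, 0.0071) and Dcn (1.01 ± 0.24, 0.00986), rose, 3 when adjusted over the list alone (camera adjusted p = 4.78e-05; adjusted p = 0.0627 with an estimated correlation); at 3 months 0 of 4 did (0.592). Of 29 hepatocyte genes 0 passed at 1 month and 5 fell at 3 months, 6 and 11 when adjusted over the list alone (0.000288 and 2.13e-05; 0.149 and 0.148 with an estimated correlation). In the lipid storage list 2 of 11 passed at 1 month, Fabp1 and Ehhadh, and 2 at 3 months, Cd36 and Vnn1, all higher (0.000288 and 0.0405; 0.0817 and 0.274 with an estimated correlation). Over the list alone 2 were higher at 1 month, and 5 higher and 2 lower at 3 months. Fabp1 (0.81, adjusted p = 0.0531) and Ehhadh (0.72, 0.0893) were positive at 3 months too, as were Cd36 (0.81, 0.321) and Vnn1 (1.05, 0.316) at 1 month. Of 6 fatty acid synthesis genes Scd1 alone rose, at both times, with 2 and 1 higher over the list alone (0.46 and 0.000124; 0.615 and 0.0535 with an estimated correlation). The sterol (0.0697 and 0.468), leukocyte (0.46 and 0.126) and bile acid lists (0.778 and 0.363, with 1 of 14 lower at 1 month and 1 at 3 months, and over the list alone 2 higher and 1 lower, then 1 higher and 2 lower) did not pass. The fatty acid synthesis median was -0.17 at 1 month while its test pointed up. The diet effect was higher at 3 months than at 1 month for fatty acid synthesis (0.00386; adjusted p = 0.132 with an estimated correlation) and lower for matrix genes (0.0108; adjusted p = 0.196 with an estimated correlation), with 0 genes passing by edgeR. None of 4 biliary epithelial genes had the counts to be tested, and pancreatic acinar genes are not analysed here.

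A group of 6 X-linked miRNAs, Mir743, Mir883a, Mir741, Mir880, Mir881 and Mir871, lies at 66776757 to 66810504 of chromosome X (mm10). From 1 month to 3 months all 6 had positive log2 values in chow mice, with Mir741 passing by edgeR (median 1.06; camera adjusted p = 4.35e-06 among 16 groups of neighbouring miRNAs; adjusted p = 0.296 with an estimated correlation). In HFCF mice 5 of 6 were negative and 0 passed (median -0.40; 0.384). At 3 months 4 of 6 were lower with the diet by edgeR and 6 of 6 were negative (median -1.40). The camera adjusted p was 0.00384, and 0.54 with an estimated correlation. For the difference of diet effects the group had a camera adjusted p = 0.0047 at the preset correlation. With an estimated correlation it was 0.706, so a difference for the group is not settled. Of the 6, Mir741 passed for this difference by edgeR, as given above. All are scarce, with Mir741 at 13.7 ± 4.71 CPM in chow mice at 3 months.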
